A study of Bos taurus with 6 samples.

How the data were processed

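Total RNA was taken from exosomes precipitated from serum or plasma and from longissimus dorsi tissue collected 24 hours after slaughter, per the labels' protocols. The labels name neither which blood fraction each exosome pool came from nor whether both tissues came from the same animals. RNA of 7 animals (high yield) or 4 animals (middle and low yield) was pooled, and 100 ng was labelled with cyanine 3 and hybridised to 1-colour bovine miRNA arrays.

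Spot intensity was extracted with Agilent Feature Extraction 10.10.1.1, which subtracted the local background, per the file headers; these intensities were not normalised between arrays. The software also gave median spot and background intensities, a summed intensity per miRNA, set to 0.1 where a miRNA was not detected, and flags per spot. The deposited value table held log2 values. Set against the arrays, each column equalled the log2 summed intensity minus 1 constant per array, to 1 decimal; which percentile the constant is was not given in the sources used here. Column medians were -12.0, -9.2 and -9.5 for high-, middle- and low-yield exosomes and -9.9, -12.5 and -12.5 for muscle. The low-yield muscle column of that table equalled the middle-yield muscle column in all 809 rows and did not match its own array (SD of the difference 2.62, against 0.0163 for the middle-yield array). That column was not used, and the table served only as an alternative.

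Each array held 48540 miRNA spots, 15 to 30 per probe, for 1755 probes; 711 miRNAs had 2 probes, 59 had 3 and 39 had 4. Spots flagged as outliers (1.36% to 4.59% per array) were left out, and no spot was saturated. Background-subtracted intensities were divided by the 75th percentile of the array over 95 probes well above background on all 6 arrays, set to a common floor of 0.0395 and averaged over spots on the log2 scale. The floor was the median over arrays of the 1st percentile of scaled signal among spots well above background. A probe counted as well above background when at least 0.5 of its spots did. A miRNA was represented by its probe of highest mean level; of the 111 calls between tissues, 107 had another probe above background, and 4 of these pointed the other way. On the exosome arrays of high, middle and low yield, 171, 103 and 106 miRNAs were well above background, and on the muscle arrays 101, 211 and 269. The median SD between spots of a probe was 0.081.

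Tissues were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 over the 219 miRNAs well above background on at least 2 arrays of a tissue (4 residual degrees of freedom), with Benjamini-Hochberg adjustment. Lists with at least 3 tested members were compared by camera with a preset correlation of 0.01, with an estimated correlation and with fry beside it. No list passed with an estimated correlation (adjusted p from 0.309 to 0.853). By fry, which asks whether the miRNAs of a list move on balance in 1 direction, 11 of 13 lists had an adjusted p under 0.05. Grades were compared within a tissue by counting miRNAs at least 2-fold apart among those well above background on both arrays. List medians were placed among 10000 random lists of the same size matched on level in 5 bins, and called below the 2.5th or above the 97.5th percentile. Grade in both tissues together was fitted with tissue and grade as additive terms over the 57 miRNAs well above background on all 6 arrays. Figures were drawn with matplotlib 3.10.9.

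The sample groups, the tests, the 15 miRNA lists, the alternatives and the rule for miRNAs named were fixed before the data were examined. Of the alternatives, the first scan alone, leaving out the 3 arrays of low labelling spike-in, the scan as a block for lists and as a further term were added later. The rule took the 8 largest differences either way between tissues among calls measured on all 6 arrays, and up to 4 either way measured in 1 tissue alone. Within each tissue it took the 6 largest grade differences either way. In applying it, miRNAs with an array at the floor were passed over, which the rule had not said: without this, miR-188 and miR-489 would have stood in place of miR-494 and miR-486 in exosomes, and miR-2476_v18.0 in place of miR-2316 in muscle, so all are named. The rule added those at least 2-fold apart in the same direction in both tissues and examples from the lists. Members of more than 1 list numbered 13. The alternatives were other scalings, normexp background correction with an offset of 50, summed signals, the mean over probes, a floor 0.5 times or 2 times as high, the deposited table, filters, blocks, moderation, thresholds and leaving out each array. Normexp used median spot signals because the files held no mean signal. On simulated data with 219 miRNAs, the tissue comparison recovered 52% of planted log2 changes of 1, 81.3% of 2 and 96.7% of 4, and 4.24% of calls were false. No floor was applied to the simulated values. In the data, 73 of the 111 calls were limited by the floor or background in the dimmer tissue, so these rates do not describe them.

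Files recorded 1 slide number and 2 scans. The local background was 59 to 71 units in the first scan and 34 to 36 in the second, which held the middle-yield and low-yield muscle arrays. The number of arrays limits the precision, and the signal over background differed between them: negative controls had an SD of 6.47 to 43.3 units against a scaling signal of 694.6 to 11250 units. The array design names the bovine build UMD_3.1, and the gene table used here was of another assembly, ARS-UCD2.0, so no coordinates are given; 710 miRNAs matched 1 hairpin gene in it, 78 more than 1 and 21 none.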

Results

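MicroRNA (miRNA) levels were measured in 6 pooled RNA samples from Korean cattle (Hanwoo) steers aged 29 or 30 months. Carcasses had been classed by meat yield grade, and the question was which miRNAs of the circulation and of muscle differ between grades. Each grade gave 1 pool of RNA from exosomes, the small vesicles precipitated from blood, and 1 pool from the longissimus dorsi, the long muscle of the back. The high-yield pools held 7 animals, and the middle-yield and low-yield pools 4 animals each. Each pool was hybridised to 1 array, so no tissue and grade had a replicate, and p-values between tissues measure only the spread between pools of different grade.

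The arrays carried probes for 809 bovine miRNAs, of which 277 were well above background on at least 1 array and 57 on all 6. Most were seen in the high-yield exosome pool (171) and in the middle-yield and low-yield muscle pools (211 and 269). The 75th percentile of signal differed 16.2-fold between arrays for 100 ng of input RNA, from 694.6 units in high-yield muscle to 11250 units in low-yield muscle. The labelling spike-in lay outside the range set by the scanner software on the middle-yield and low-yield exosome arrays and on the high-yield muscle array. Levels are given on the log2 scale relative to the 75th percentile of each array, with a floor of -4.66.

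Muscle and exosome pools differed in 111 miRNAs, with 53 higher in muscle and 58 higher in exosomes (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 pools per tissue). For 73 of them an array of the dimmer tissue was at the floor or not well above background. Values at the floor have little or no spread: miR-206 had an SD of 0 in exosomes. Adjusted p-values of such miRNAs belong to the floored difference, not to the fold bounds printed beside them, and may be too small. At the bounds explained below, 6 of the calls kept their direction but were under 1.5-fold. Well above background on all 6 arrays were 38 calls, 14 higher in muscle and 24 higher in exosomes. The widest differences were those of miR-1, miR-133a, miR-133b and miR-206, miRNAs of striated muscle. miR-133a, a miRNA of skeletal and cardiac muscle, was at least 449-fold higher in muscle (limma adjusted p = 9.81e-06), and miR-206, which is specific to skeletal muscle, at least 110-fold higher (limma adjusted p = 6.42e-06). In the opposite direction, miR-451, the abundant miRNA of red blood cells, was 80.7-fold higher in exosomes (log2 difference -6.33, SE 0.63, limma adjusted p = 0.00125). The liver miRNA miR-122 was at least 10.4-fold higher in exosomes (limma adjusted p = 0.000268) and was not well above background in any muscle pool.

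Among miRNAs measured on all 6 arrays, the largest differences towards muscle were those of miR-365-3p and let-7a-5p. miR-365-3p lay at 2.59 ± 0.18 in muscle and -3.31 ± 0.14 in exosomes (SD, n = 3 pools). let-7a-5p lay at 2.69 ± 0.45 and -3.17 ± 1.07. The endothelial miRNA miR-126-3p was higher in muscle by 4.46, let-7g by 3.79, miR-26b by 3.66, let-7b by 3.55, miR-30b-5p by 2.99 and miR-145, a miRNA of smooth muscle, by 2.96 (log2, limma adjusted p from 0.00121 to 0.0243). miR-378c and miR-499, the latter encoded within a myosin heavy chain gene, were well above background in every muscle pool and in no exosome pool, at least 31.9-fold and at least 30.9-fold higher. Each bound sets the mean of the bright tissue against the lowest level of a probe well above background on each array of the dim tissue, or the miRNA's own level where higher.

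Towards exosomes, miR-2412 followed miR-451 with a log2 difference of -6.01 (SE 0.34), at 3.38 ± 0.51 in exosomes and -2.64 ± 0.37 in muscle (SD, n = 3 pools). The differences of miR-1224, miR-1246, miR-2881, miR-2374, miR-2455 and miR-1777a were -4.37, -3.92, -3.68, -3.65, -3.63 and -3.36 (limma adjusted p from 0.000837 to 0.0107). miR-760-5p was well above background in every exosome pool and in no muscle pool, but at least 1.61-fold higher at an adjusted p of 0.152 (limma).

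**Figure D1:**
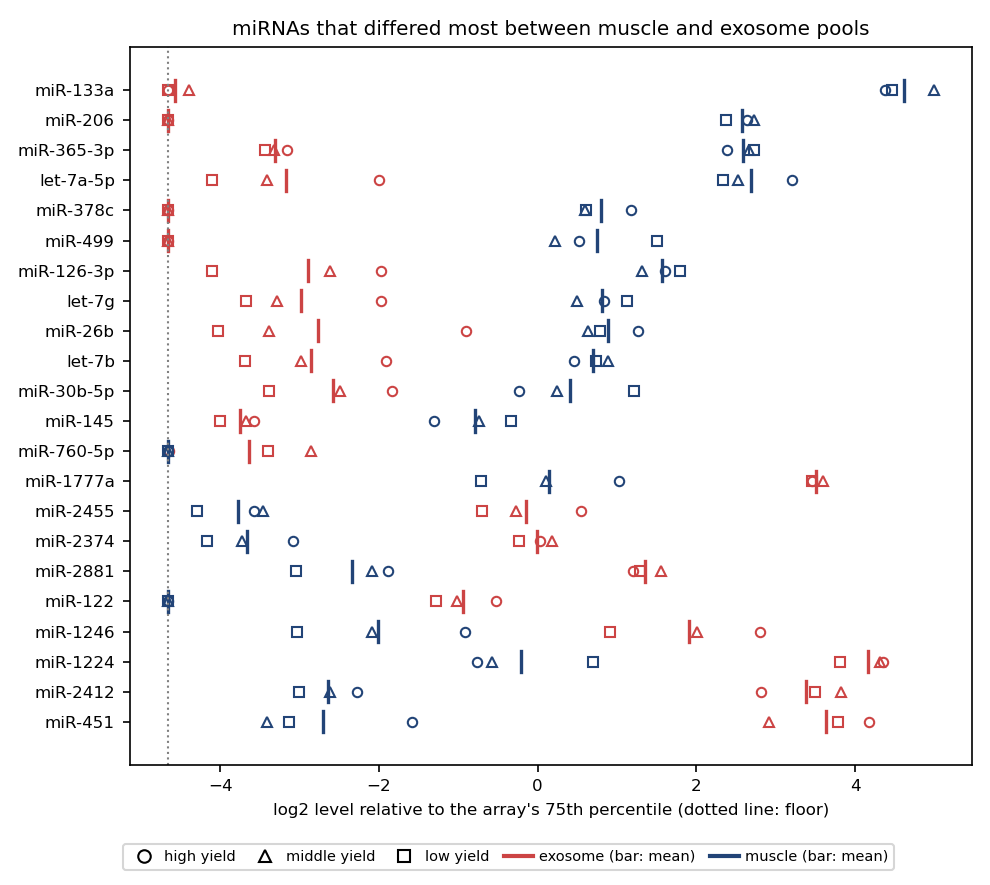
Levels of the 22 miRNAs singled out between tissues, with log2 level relative to the 75th percentile of the array on the horizontal axis. Each symbol is 1 pool, shaped by yield grade and coloured by tissue, bars are means of 3 pools and the dotted line is the floor at -4.66; miR-133a lies near the floor in exosomes and at a mean of 4.61 in muscle, and miR-451 lies at means of 3.63 and -2.71.

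Of the 7 tested miRNAs known to be enriched in muscle, 5 rose in muscle and 2 did not pass (camera, adjusted p = 0.00498; adjusted p = 0.309 with an estimated correlation). They included miR-1, at 6.07 ± 1.41 in muscle and -4.55 ± 0.10 in exosomes, and miR-133b, at 4.92 ± 0.41 and -4.12 ± 0.89 (SD, n = 3 pools). All 9 tested members of the let-7 family rose in muscle, from a log2 difference of 1.74 for let-7i to at least 90.1-fold for let-7f (camera, adjusted p = 0.00177; adjusted p = 0.517 with an estimated correlation). Of 17 miRNAs of muscle growth and differentiation, 7 rose and 1 fell in muscle (camera, adjusted p = 0.0269; adjusted p = 0.517 with an estimated correlation). miR-378b was at least 109-fold and miR-26a at least 27.7-fold higher in muscle, miR-128 was higher by 2.84 (log2), and miR-221 was at least 3.88-fold lower. With a mean of 1.59, or 1.55 with members dim in 1 tissue set to their bounds, this list no longer passed with the scan as a block (mean 1.40, camera, adjusted p = 0.117) or the first scan alone (1.93, 0.056). Nor did it without the 3 arrays of low labelling spike-in (1.23, 0.111), with quantile normalisation (1.14, 0.0805), with normexp (1.24, 0.0687), with no filter on dim probes (1.17, 0.0953) or above background on all 6 arrays (1.64, 0.0514).

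The cluster from miR-17 to miR-92a and its paralogues fell in muscle in 9 of 10 tested members, among them miR-19a, at least 5.71-fold lower, and miR-106a, at least 3.78-fold lower (camera, adjusted p = 0.00588; adjusted p = 0.517 with an estimated correlation). Of 35 miRNAs first catalogued in cattle, 17 fell and 1 rose in muscle (camera, adjusted p = 0.00107; adjusted p = 0.309 with an estimated correlation). miR-2389 was at least 12.4-fold and miR-2309 at least 9.53-fold lower, and miR-2288 at least 1.52-fold higher. Of the 17, miR-2392 kept no direction at its bound, being well above background on 1 exosome array and 2 muscle arrays, and it was the only such call among the 111. Of the 35, 28 were at the floor or not well above background on an array of the dimmer tissue; with these at their bounds the mean of the list was -1.14 in place of -1.26. Above background on all 6 arrays neither list passed (camera, adjusted p = 0.26 and 0.0503); nor did the first without the 3 arrays of low labelling spike-in (0.159), or the second with no filter on dim probes (0.519). Counts adjusted over the list alone were 5, 9, 8, 9 and 18 for the 5 lists, in the order given; for the lists that follow they equalled the counts over all tested.

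The other lists did not pass as groups, although the erythrocyte list did without the middle-yield exosome array (camera, adjusted p = 0.0401) and, with no filter on dim probes, the erythrocyte and leukocyte lists did (0.0249 and 0.0123). Of the erythrocyte list, 2 of 7 members fell in muscle, miR-451 and miR-92a (camera, adjusted p = 0.114), and of the leukocyte list 2 of 5, miR-223 at least 34.9-fold and miR-142-5p at least 16-fold lower (camera, adjusted p = 0.151). The platelet list held 3 members higher and 1 lower in muscle among 9 (camera, adjusted p = 0.219), the vascular list 4 and 1 among 7 (camera, adjusted p = 0.105) and the liver list 2 and 1 among 5 (camera, adjusted p = 0.846). Of the adipogenesis list 3 of 12 were higher in muscle (camera, adjusted p = 0.146), of the miR-30 family 2 of 7 (camera, adjusted p = 0.151) and of the DLK1-DIO3 cluster 0 of 6 (camera, adjusted p = 0.768). No epithelial list member was tested, and of the neural list miR-128 alone.

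All 111 miRNAs kept 1 direction in the 3 grades. The first scan held the 3 exosome arrays and the high-yield muscle array. With the scan as a block 101 miRNAs passed, 91 of them among the 111, and the first scan alone gave 83, of which 80 were shared (limma). Both rest on the high-yield array for the level of muscle, the 1 muscle array in the first scan. In the first scan alone the spread comes from the exosome arrays (2 residual degrees of freedom), and muscle is assumed to vary as they do.

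Between grades, exosomes of the high-yield pool held more of the miRNAs abundant in platelets than those of the low-yield pool. The myeloid miRNA miR-223 was higher by 2.74, miR-21-5p by 2.55 and miR-126-3p by 2.13 on the log2 scale. miR-26b had the largest difference towards high yield, 3.13, and let-7a-5p and miR-1246 were higher by 2.10 and 1.90. Over all settings miR-26b differed by 1.84 to 3.97, miR-126-3p by 0.96 to 2.81, let-7a-5p by 0.94 to 2.78 and miR-1246 by 0.84 to 2.6. In the low-yield pool miR-26b, miR-126-3p and let-7a-5p lay close to the floor, at -4.03, -4.1 and -4.1. On that array the SD of negative controls (43.3 units) exceeded the floor (38.4 units), so the differences of these miRNAs are uncertain in size. miR-2413, miR-2478, miR-1260b and miR-2309 were lower in the high-yield pool, with differences of -3.57, -3.42, -3.42 and -2.57. miR-494 and miR-486, a miRNA of red blood cells and muscle, followed at -1.34 and -1.10. miR-188 and miR-489, at or near the floor in the high-yield pool, differed by -1.83 and -1.39.

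With 1 array per grade these differences have no replicate check and no test was made. The SE from repeated spots, which covers technical error within an array, was between 0.01 and 0.06 for the 12 miRNAs apart from this pair. Of 105 miRNAs measured on both arrays, 30 were at least 2-fold apart, with 21 higher and 9 lower in the high-yield pool. The median difference was 0.31, and relative to it 15 were higher and 10 lower. The split depended on scaling: it was 15 and 17 after quantile normalisation, 8 and 8 after normexp background correction, 53 and 5 with all probes in the scaling, 41 and 8 with summed signals and 19 and 19 in the deposited value table.

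The platelet list stood apart from random lists matched on level: all 5 measured members were higher in the high-yield pool, with a median of 2.13 at percentile 100. Of these, miR-223 is also in the leukocyte list, miR-126-3p in the vascular list and miR-24-3p in the growth list. Muscle growth and differentiation also stood apart, with 9 of 9 members higher and a median of 1.25 at percentile 100. Its members included miR-23a (1.84), miR-221 (1.47), miR-29b (1.43) and miR-27b (1.25). Both stood apart under all 10 other settings, at percentiles 98.5 to 100 for the platelet list (median 1.02 to 2.81) and 98.8 to 100 for the growth list (median 0.71 to 1.95). The growth list stood apart between middle and low yield, with 8 of 8 members higher in middle yield (median 0.87, percentile 99.6). Between high and middle yield its median was 0.25 (percentile 49.7), equal to that of all measured miRNAs. The erythrocyte list, with miR-451 at 0.39 and miR-486 at -1.10, had a median of 0.12 at percentile 27.8 (23.6 to 35.6 under the other settings, the sign turning under 2 of 10).

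For the remaining lists between high and low yield, the median was 1.74 for 4 let-7 members (percentile 94.3), 1.47 for 3 vascular members (percentile 85.3), 0.98 for 6 adipogenesis members (percentile 85.5), 0.06 for 9 members of the miR-17 cluster list (percentile 24.3) and -0.02 for 19 miRNAs first catalogued in cattle (percentile 3.42). The signs of the last pair turned under 3 of 10 settings each, but some of these settings shift all miRNAs together. Set against random lists, the miR-17 cluster list lay at percentiles 11.6 to 24.3 and miRNAs first catalogued in cattle at 0.71 to 31.6, standing apart under 3 of 10. The let-7 list stood apart under 6 of 10 settings and the vascular list under 1.

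The middle-yield exosome pool lay nearer to the low-yield pool. High and middle yield differed at least 2-fold in 22 of 102 miRNAs, 13 higher and 9 lower, and middle and low yield in 10 of 98, 9 higher and 1 lower. Relative to median differences of 0.25 and 0.35, the splits were 9 and 12, and 3 and 8. miR-1260b was at -3.15 in the high-yield, 0.62 in the middle-yield and 0.27 in the low-yield pool. miR-223 was at 2.27, 0.60 and -0.47 in the same order. For high against middle yield the split was 9 and 16 after quantile normalisation, 4 and 9 after normexp, 26 and 9 with all probes in the scaling, 32 and 10 with summed signals and 15 and 23 in the deposited value table. For middle against low yield it was 5 and 5 after quantile normalisation, 3 and 1 after normexp, 21 and 0 with all probes in the scaling, 13 and 5 with summed signals and 8 and 8 in the deposited value table.

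In muscle, miR-1, like miR-133a a miRNA of skeletal and cardiac muscle, was higher in the high-yield than in the low-yield pool by 2.76 on the log2 scale. miR-1246 was higher by 2.11, miR-2305 by 1.95, miR-1777a by 1.73, miR-6119-5p by 1.72 and miR-2316 by 1.58. Over all settings the smallest differences of these miRNAs were 1.06, 1.73, 1.51, 0.9 and 0.73, in that order. Lower in the high-yield pool were miR-1260b (-2.14), miR-22-5p (-1.99), miR-99a-5p (-1.83), miR-29c (-1.76), miR-1224 (-1.47) and miR-30b-5p (-1.45). miR-2476_v18.0, at the floor in the low-yield pool, was higher by 1.63. Among the other miRNAs of striated muscle, miR-133a differed by -0.07, miR-133b by 0.02, miR-206 by 0.27 and miR-499 by -0.98. After quantile normalisation miR-1 differed by 0.00, which follows from miR-1 holding the highest level on both arrays. In high-, middle- and low-yield muscle miR-1 lay at 7.6, 5.76 and 4.84, on arrays with scaling signals of 694.6, 4287 and 11250 units. Its level thus fell as the arrays grew brighter, so array brightness was not separated from grade for miR-1.

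**Figure D2:**
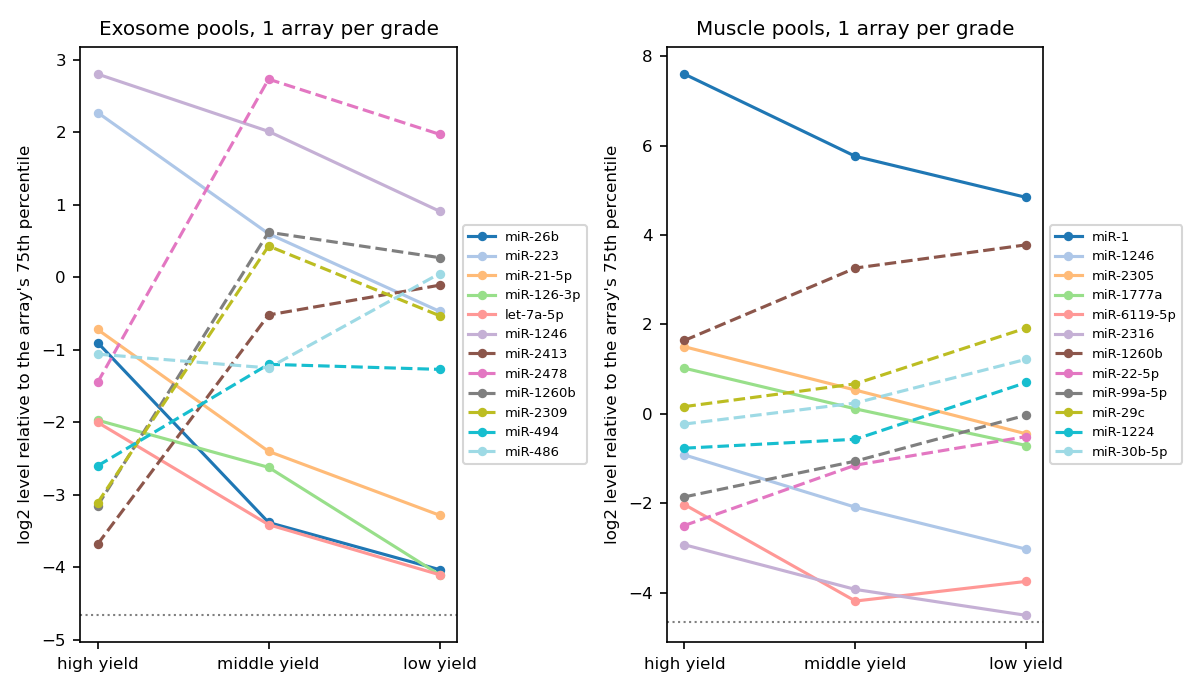
Levels of the 12 miRNAs singled out per tissue across high, middle and low yield, with 1 array per point and log2 level relative to the 75th percentile of the array on the vertical axis. Solid lines are miRNAs higher in high than in low yield, dashed lines the reverse and the dotted line the floor; miR-1260b in exosomes goes from -3.15 to 0.27, and miR-1 in muscle from 7.60 to 4.84.

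Of 101 miRNAs measured in both muscle pools, 38 were at least 2-fold apart, 20 higher and 18 lower in the high-yield pool, with a median difference of 0.02. After normexp correction the split was 29 and 10, and with all probes in the scaling 17 and 24. Of 9 measured miRNAs first catalogued in cattle, 8 were higher in the high-yield pool, with a median of 1.30 at percentile 99.2 of random lists; miR-2305, miR-2476_v18.0, miR-2316 and miR-2328-3p led with 1.95, 1.63, 1.58 and 1.56. The list no longer stood apart with normexp (median 1.30), with the higher floor (0.63) or when being above background on 1 of the arrays sufficed (0.00, with 26 of 51 members at the floor on both arrays). Muscle growth and differentiation had a median of -0.72 (percentile 4.89) with 4 of 11 members at least 2-fold lower, among them miR-29a (-1.42) and miR-128 (-1.08).

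The other muscle lists lay within the range of random lists: muscle-enriched miRNAs had a median of -0.07 (percentile 57.8, sign turned under 1 of 9 settings), adipogenesis -0.76 (percentile 7), erythrocyte 0.58 (percentile 84.7), platelet -0.46 (percentile 18.7), vascular -0.26 (percentile 25.1), let-7 0.42 (percentile 82), miR-30 -0.45 (percentile 44) and the miR-17 cluster list -0.78 (percentile 6.65). Against middle yield, high-yield muscle differed at least 2-fold in 20 of 101 miRNAs, 18 higher and 2 lower, or 12 and 8 relative to a median difference of 0.28. Middle and low yield differed in 22 of 211, 1 higher and 21 lower. The first split was 6 and 28 with all probes in the scaling, 9 and 4 after quantile normalisation, 14 and 9 with summed signals, 13 and 16 in the deposited value table and 12 and 8 with scaling per tissue. The second was 21 and 8 with all probes in the scaling, 9 and 10 after quantile normalisation, 9 and 21 with summed signals and 7 and 14 with scaling per tissue. The high-yield muscle array was scanned apart from the other 2 muscle arrays, so in muscle high yield and scan cannot be told apart.

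**Figure D3:**
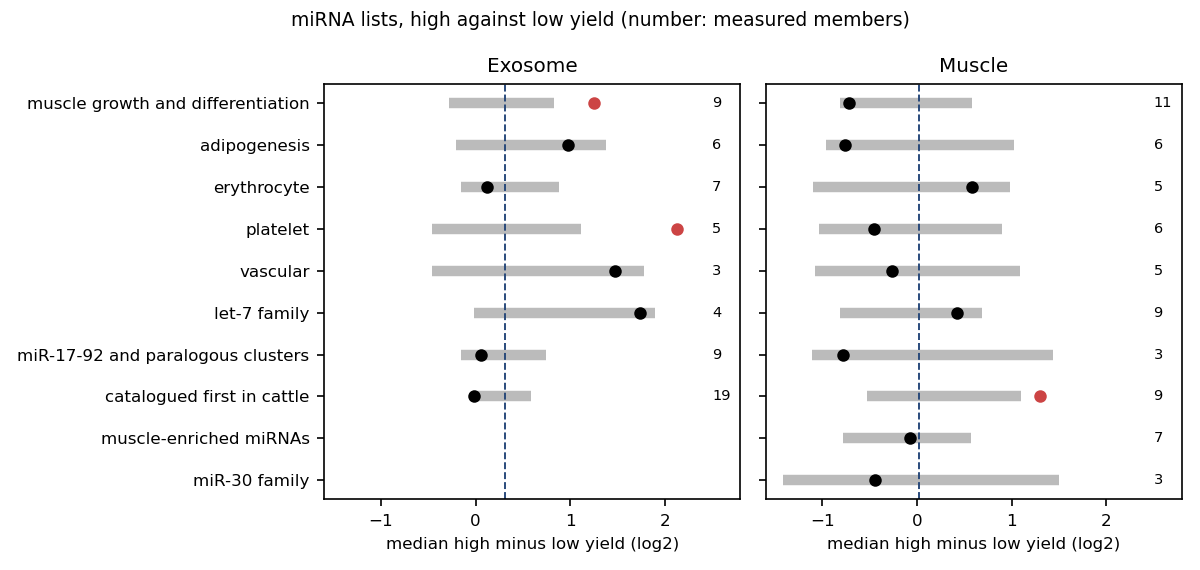
Median high minus low yield difference (log2, horizontal axis) of each miRNA list with at least 3 measured members, in exosomes and in muscle. Points are list medians, red where outside the central 95% of 10000 random lists (grey bars), dashed lines mark the median of all measured miRNAs and numbers the measured members; the platelet list lies at 2.13 in exosomes and -0.46 in muscle.

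Exosome and muscle pools shared few grade differences: of 60 miRNAs measured in both, 26 differed in the same direction between high and low yield. At least 2-fold apart in both tissues were 5 in the same direction and 3 in opposite directions. Whether 5 exceeds the number that unrelated differences would give was not tested. miR-1260b and miR-494 were at least 2-fold lower, and miR-1246, miR-186 and miR-21-5p at least 2-fold higher, in the high-yield pools of both tissues. miR-186 differed by 1.34 in exosomes and 1.35 in muscle, and miR-494 by -1.34 and -1.25. Of these, miR-1260b alone stayed at least 2-fold apart in both tissues under all settings. At their smallest over all settings, miR-186, miR-1246 and miR-494 differed by 0.43, 0.84 and -0.64 in exosomes, and miR-21-5p by 0.74 in muscle. The fit with tissue and grade as additive terms took the exosome and the muscle pool of a grade as its replicates. Its SE measures how far grade differences disagreed between tissues, not the spread between pools or animals of a grade. In this fit 1 of 57 miRNAs passed, and 7 at an unadjusted p under 0.05 (limma). miR-1260b differed by -2.78 (SE 0.61, 2 residual degrees of freedom, limma adjusted p = 0.0351). The next were miR-1246 at 2.00 (limma adjusted p = 0.0707) and miR-21-5p at 1.94 (limma adjusted p = 0.112). Over all alternatives the adjusted p of miR-1260b ran from 1.8e-05 to 0.621.

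Across the 60 miRNAs measured in the high-yield and low-yield pools of both tissues, the 95% intervals of both correlations included 0. Pearson's r was 0.11 (95% interval from resampled miRNAs -0.23 to 0.35) and Spearman's rho -0.10 (-0.36 to 0.16). These are correlations across miRNAs, which are not independent replicates.

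**Figure D4:**
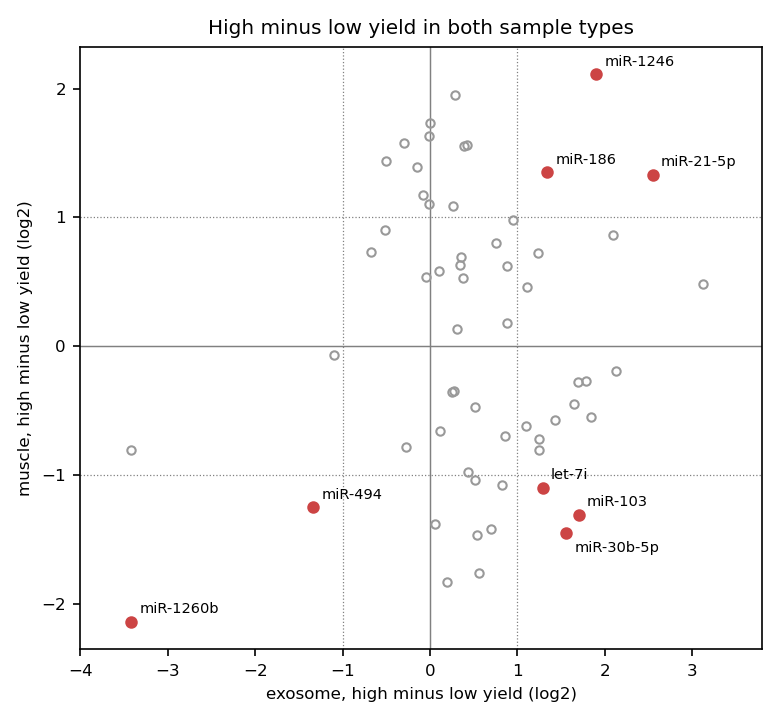
High minus low yield difference in exosomes (horizontal axis, log2) against that in muscle (vertical axis, log2) for 60 miRNAs, 1 point each. Red points are miRNAs at least 2-fold apart in both tissues, and dotted lines mark a log2 difference of 1; miR-1260b lies at -3.42 and -2.14.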

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

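All tests weighed here were chosen, and their bounds set, after the results they bear on had been seen, so what they leave standing is a hypothesis. Each rests on single arrays per tissue and grade. The labelling spike-in followed high against low yield in both tissues: its reading was in range for high-yield exosomes (3.41) and out of range for middle and low yield (2.49 and 2.33), and in muscle out of range for high yield (1.93) and in range for the others (3.39 and 3.53). Within each tissue, labelling was therefore not separated from grade for any difference of the high-yield pools below. It ran opposite ways in the 2 tissues, so a labelling effect alike in both would give high minus low differences of opposite sign.

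The difference between high and low yield had opposite signs in the 2 tissues for 3 miRNAs at least 2-fold apart in both. let-7i differed by 1.29 in exosomes and -1.10 in muscle. miR-103 differed by 1.70 and -1.31. miR-30b-5p differed by 1.56 and -1.45. The difference between tissues was not tested for any of them. All 3 were higher on the brighter array in both tissues, which was high yield in exosomes (2.98-fold) and low yield in muscle (16.2-fold). The labelling spike-in was in range on these brighter arrays, so brightness and labelling were not separated from grade.

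Platelet-abundant miRNAs were higher in exosomes of high than of low yield (5 of 5 members, median 2.13); all but miR-223 were also well above background in every muscle pool. Array brightness, as the 75th percentile of signal, was weighed on the middle-yield and low-yield arrays, 1.32-fold apart. The low-yield array was the brighter, yet all 5 members were higher in middle yield (median 1.05). This lay at percentile 99.2 of random lists matched in 5 bins on the high minus low difference, which shares the low-yield array. The list was singled out by that difference, and 5 bins match its largest members only coarsely. The percentile therefore does not decide whether brightness is the whole cause. Between the high-yield and middle-yield arrays, 3.94-fold apart, brightness also stays open. The low-yield array was noisier than the middle-yield one (SD of negative controls 43.3 against 11.7), but noise acting alike on all dim miRNAs is argued against by the list at percentile 100 of random lists matched on level on that array. A common rise of all blood cell miRNAs is argued against for high against low yield by the erythrocyte list at percentile 27.8, with members from -1.10 to 0.50 against 0.95 to 2.74 for platelet members; between high and middle yield it stays open, since the erythrocyte list was higher there too (6 of 6, median 0.83, percentile 99.6) and the platelet list lay at percentile 88.6 (median 0.65), which also leaves undecided whether a platelet RNA share falling in order of grade may contribute. A rise of white blood cell miRNAs was not tested, since the leukocyte list, which holds miR-223, had fewer than 3 measured members. Blood handling and the fraction used, serum or plasma, were not recorded per pool, and yield grade itself stays open and untested.

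miRNAs first catalogued in cattle were higher in high-yield than in low-yield muscle (median 1.30). The later scan stays open: between the middle-yield and low-yield arrays, which share it, these 9 miRNAs were all higher in middle yield (median 0.45), at percentile 99.9 of lists matched on level but 86 of lists matched on the high minus low difference, which shares the low-yield array. Array brightness could account for it, since the high-yield muscle array was 16.2-fold dimmer than the low-yield one: in exosomes 7 of these miRNAs lay at percentile 6.38 on the brighter of 2 arrays (median -0.15), which is not decisive. Brightness moving all miRNAs alike in both tissues was not settled either, with Pearson's r of -0.24 (95% interval -0.44 to 0.04) over 60 miRNAs. Yield grade was not separated from scan or brightness.

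miR-1260b, miR-2478, miR-2413 and miR-2309 were low in high-yield exosomes alone among the 3 exosome pools. A single faulty probe is argued against for miR-1260b and miR-2478, whose other probes differed by -1.65 and -4.50, but stays possible for miR-2309, whose other probe differed by -0.80, and for miR-2413, whose other probe was not well above background. Brightness stays open for miR-1260b and miR-2478, which differed by 0.52 and -0.14 (brighter minus dimmer) between muscle arrays of 1 scan, within the SD of 0.58 over all miRNAs measured there; it was not tested for the other 2. Across scans both were higher on the 16.2-fold brighter low-yield than on the high-yield muscle array (2.14 and 0.81), opposite to the exosome arrays, but scan and grade differ there too. miR-1260b was thus low in the high-yield pools of both tissues, but with 1 pool per grade and tissue a difference of yield grade and a property of single RNA pools cannot be told apart.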

How the results depend on the processing

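The tests with the first scan alone, without the 3 arrays of low labelling spike-in, with the scan as a block for lists and with the scan as a further term were chosen after the data were seen; the rest were planned. Between tissues the count of 111 stayed within 1.5 times under all alternatives except with only miRNAs above background on all 6 arrays (43 of 57 tested, fewer miRNAs by construction); leaving out 1 array at a time gave 101 to 109, and without the 3 arrays of low labelling spike-in 78 passed, 24 higher and 54 lower in muscle (53 and 58 with all arrays), 54 of the 78 shared. That left 1 exosome array against 2 muscle arrays, so the spread came from muscle alone (1 residual degree of freedom) and the lone array is assumed to vary as muscle does. A block by yield grade gave 102 calls (98 shared). Deviations of same-grade pools correlated at 0.18, 0.26 and 0.06. Those of pools of different grade were not set beside them, so whether grade pairs the pools stays open. None of the shared calls changed direction. Leaving out 1 array at a time, 5 to 6 lists passed. Of 5 lists, 1 passed above background on all 6 arrays, 0 with an estimated correlation and 3 without the 3 arrays of low labelling spike-in. For exosomes, high against low yield (30), the count was 58 with all probes in the scaling, 16 with normexp, 49 with summed signals, 47 when above background on 1 array sufficed and 49 at 1.5-fold; high against middle (22) gave 35, 13, 42, 37 and 50 in that order and 38 in the deposited table; middle against low (10) gave 21 with all probes, 4 with normexp, 18 with summed signals, 16 in the deposited table and 33 at 1.5-fold. Exosome lists standing apart (2) became 4 with quantile normalisation, 4 with normexp and 4 with the higher floor. In muscle, high against low (38) gave 62 at 1.5-fold; high against middle (20) gave 34 with all probes, 13 with quantile normalisation and 48 at 1.5-fold; middle against low (22) gave 14 with normexp and 58 at 1.5-fold. Muscle lists standing apart (1) became 0 with normexp, 0 with the higher floor and 3 when above background on 1 array sufficed, all of them other lists and lower (muscle growth, adipogenesis and the miR-17 cluster list). In both tissues together (1), 0 passed with all probes and 0 with summed signals, 4 with quantile normalisation, 4 with normexp, 2 with the mean over probes, 4 with trend and robust moderation, 3 with the scan term (where the high-yield muscle array is fitted exactly, so that these rest on the high-yield exosome array alone, with 1 residual degree of freedom) and 58 with no filter, of which 56 were above background on at most 1 array. For single miRNAs named between tissues, 443 of 478 values kept their side of the threshold, 32 lost it and 3 gained it; for lists 237 of 256 kept it. Between high and low yield, 99 of 220 values of named miRNAs in exosomes and 75 of 200 in muscle moved by more than the spread between spots. The deposited table gave no value for low-yield muscle. No called value reversed between tissues or between high and low yield. Apart from the all-6-array, estimated-correlation and no-filter settings, the cause was not tested. A floor 0.5 times as high moved the median tissue difference by 0.14. Dim arrays limit detection: 168 miRNAs were above background in low-yield muscle and not in high-yield muscle, and 0 the other way.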

Other observations

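The test by other splits of the arrays was chosen after the result was seen. The erythrocyte list as a group set the middle-yield exosome pool apart from both others, although miR-486 differed little between high and middle yield. The erythrocyte list was higher in high than in middle yield for 6 of 6 members, with a median of 0.83 at percentile 99.6 of random lists, and lower in middle than in low yield for 6 of 6, with a median of -0.86 at percentile 0; under 8 other settings the medians were 0.56 to 1.18 (percentiles 92.2 to 99.6, standing apart under 6) and -1.04 to -0.51 (percentiles 0 to 0.11). miR-451 differed by 1.27 and -0.88 in these comparisons, and miR-486 by 0.20 and -1.30. The list of miR-17 to miR-92a and paralogues was lower in middle than in low yield for 9 of 9 members (median -0.50, percentile 1.48, and 0.835 to 1.61 under the other settings). It too was higher in high than in middle yield for 9 of 9, but within the range of random lists (median 0.57, percentile 81.7). let-7 members were higher in high than in middle yield for 5 of 5 (median 1.32, percentile 99.5; 97.9 to 99.6), and the 3 vascular members were higher in middle than in low yield (median 0.95, percentile 99.2; 82.9 to 99.7, standing apart under 7 of 8). miRNAs first catalogued in cattle had a median of -0.24 between high and middle yield (percentile 1.1; 1.1 to 6.43, standing apart under 6 of 8), whose sign turned under 2 of 8 settings. These percentiles describe single arrays, and no explanation was tested.

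Middle-yield and low-yield muscle, which share a scan, differed in 4 lists: muscle-enriched miRNAs had a median of 0.37 (percentile 97.8), muscle growth and differentiation -0.39 (percentile 0.93), adipogenesis -0.64 (percentile 0.39) and the miR-17 cluster list -0.81 (percentile 2.09). These lists stood apart under 7, 3, 7 and 3 of 8 other settings, in that order. No sign turned, but the first pair of medians reached 0.00. The low-yield array was 2.62-fold brighter, so brightness was not separated from grade. Many miRNAs measured here were at the floor on both arrays, among them 21 of 33 first catalogued in cattle. This can narrow the range of the random lists.

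The 2 arms of a hairpin differed in direction or size between grades in muscle; these hairpins were chosen after their values were seen. miR-22-3p lay at -0.08, -1.17 and -1.07 in high-, middle- and low-yield muscle, while miR-22-5p lay at -2.50, -1.15 and -0.51. Between high and low yield miR-126-3p differed by -0.19 and miR-126-5p by -1.40. In high-, middle- and low-yield muscle miR-199a-3p lay at -0.72, -0.94 and -0.89, and miR-199a-5p at -3.34, -2.41 and -2.02. In each hairpin the 5p arm was lower in high than in low yield. It was the dimmer arm on every muscle array for miR-126 and miR-199a, but for miR-22 only on the high-yield array. The high-yield array was 16.2-fold dimmer than the low-yield one and scanned apart, so brightness and scan were not separated from grade.

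For the 111 miRNAs that separated muscle from exosomes, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many calls, the real one, and the highest of the other splits gave 0. The splits are too few for a share under 0.05.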
